A study of Mus musculus with 6 samples.

How the data were processed

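RNA was measured in 6 libraries of sorted CD4+CD8+ thymocytes, 3 from mice without miR-181a-1 and miR-181b-1 and 3 from wild type mice, grouped by genotype as given in the labels. Per the labels' protocols, cells were sorted to high purity, RNA was extracted with either Trizol or a column kit, and libraries were made with the TruSeq RNA kit. The labels do not tie an extraction method to a library. The submitters' processing notes name TopHat2, an aligner of spliced reads, and the mouse genome build mm9, without versions. The counting or testing tool, the gene annotation and the treatment of reads that match several genes are not given in the sources used here.

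The deposited table held 37867 gene models with positions in mm9. Per the file headers, it gave 1 FPKM value per genotype, the authors' log2 ratio of wild type over knockout, a test statistic, which is a score on the scale of a normal z, a p-value, a q-value and a test status. The authors' status marked 13834 models as tested, 23944 as not tested, 66 as failed, 16 as having too little data and 7 as having too much. The highest mean of an untested model was 0.314 FPKM. Checked on the file, the deposited q-values were Benjamini-Hochberg adjusted p-values over the tested models (largest difference 1.89e-06), and the deposited p-values were normal tails of the test statistic (largest difference 2.82e-06). The table pools the libraries of each genotype, so no value of a single library, no depth and no count of reads was used here, and precision is known only through the deposited statistic. FPKM divides by library size and transcript length, so a change in a few abundant transcripts moves all other values, and base composition is not part of the unit.

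The design fixed before the data were examined foresaw 3 cases, and the table met the last of them: no test was run on the libraries, and the genes changed are those with a q under 0.05 in the authors' deposited table. The log2 ratio was turned to knockout over wild type. The standard error implied by the deposited test statistic is the size of the log2 ratio divided by that statistic, with a median of 0.35 over the tested models. The rule for named genes was also fixed then. It took 8 genes of the miR-181 literature and the targeted locus, up to 3 called members per direction of each of 27 gene lists by smallest p, and the 12 highest and 12 lowest ratios among called genes with a symbol and a mean of at least 2 FPKM. Where several models had a matched symbol in common, 1 was kept, a tested one first and then the one with the highest mean, and models without a matched symbol were not ranked. It gave 91 genes, some of which are not reported here. Other genes in the text were chosen after their values were seen.

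Table names were matched to symbols and transcripts of the GENCODE M21 annotation of GRCm38, which served for sequences and for distances within that build. No coordinate was converted between builds. GC content, transcript length and 3′ UTR sequence came from 1 reference transcript per gene. Genes whose reference transcript was longer than 1.2 times the span of their model in the table were left out, 65 among those tested, and this filter was added after implausible transcripts had been seen among called genes. A reference isoform that is not the one expressed remains possible. For 8742 coding genes with a mean of at least 1 FPKM, a robust regression of the log2 ratio on cubic splines with 5 pieces of GC content and log2 length was fitted with statsmodels, and the residual is called the value after removal of the GC and length trend. It was divided by the implied standard error and adjusted by Benjamini-Hochberg. On simulated data with the fitted trend over 8742 genes for this comparison, 45% of genes changed by 1 log2 unit and 87% of those changed by 2 were recovered, with 3 unchanged genes called. Without the removal, 56% and 92% were recovered, with 1855 unchanged genes called. Genes that carried only the fitted trend were counted as unchanged. These counts therefore do not show whether the trend is technical or an effect of the genotype. The simulated noise was drawn with the same implied standard errors that the calls used. Few false calls thus followed from the setting and do not bear on the calls in the data.

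For each list with at least 5 tested members, 22 of 27, the median log2 ratio was placed among 10000 random lists of the same size matched in 20 groups of mean expression, as a description of this table and not a test. The same was done with 20 groups of GC content, each in 4 groups of expression, and with the residuals, over 9656 tested coding genes with GC content. That comparison was first run on genes of at least 1 FPKM and was widened because some lists then had too few members with a value, and the lowest share of a list's tested members with a GC value is now 97.5%. As a check on the residuals of 8742 genes, 8 of 100 lists of 20 randomly drawn genes fell outside the central 95%. All 100 lay above it once 0.5 log2 units had been added to their members. The deposited ratios, which spread more widely, and lists of genes regulated together were not checked in this way.

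Sites of miR-181 were searched in the 3′ UTR of 8698 coding genes as the 8-base match TGAATGTA or the 7-base matches TGAATGT and GAATGTA, and 44 genes without an annotated 3′ UTR were not searched. The seed was shuffled 50 times with a fixed random seed. The planned permutation test over genes is not given, since genes of a table with 1 value per genotype are not replicates, and the shuffled seeds stand in its place. Every 7-base word in at least 100 UTRs was ranked by the mean difference after trend removal. That ranking was first run by a scaled difference with at least 200 UTRs, and both are given in the closing section. Centring, removal of the trend, matching on GC content and leaving out overlapping models were added after the data had been seen, beside the alternatives planned before. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.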

Results

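The data covered double-positive thymocytes, the CD4+CD8+ stage at which developing T cells are selected on their newly made receptor, sorted from mice lacking the microRNA genes miR-181a-1 and miR-181b-1 and from wild type mice of the C57bl6 strain. There were 3 sorted populations of each genotype. Their RNA was sequenced, and the authors deposited one table with 37867 gene models, 1 FPKM value per genotype for each model, and their own comparison. Values of the single populations were not used here, so no SD is given. Every error is the standard error of the log2 ratio implied by the deposited test statistic. Read counts were not used here, and the depth of each library is unknown. The labels do not say whether the populations of a genotype came from separate animals. How the deposited test statistic was computed is not given in the sources used here. Whether the p values measure a spread between these samples is therefore unknown, and any such spread may be technical. FPKM summed to 297352 in the knockout and 360688 in the wild type. All ratios below are knockout over wild type.

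The transcript that spans the targeted microRNA genes was 46.6-fold higher in the knockout. The model, listed under the names AK076660 and CS444488 on chromosome 1 from 139794044 to 139874930 (mm9), stood at 156 FPKM in the knockout and 3.35 FPKM in the wild type. Its log2 ratio was 5.54 with an implied standard error of 0.27, and its q is listed as 0 in the authors' deposited table. Its neighbours did not pass the threshold. Ptprc, which encodes the phosphatase CD45, stood at 593 against 423 FPKM (q = 0.321 in the authors' deposited table), and Nek7 stood at 22.4 against 14.7 FPKM (q = 0.0814 in the authors' deposited table). The model lies 85061 to 165947 bases from the lowest coordinate of Ptprc in mm9. In the GENCODE annotation of GRCm38, Mir181a-1 and Mir181b-1 lie 96406 and 96222 bases from the lowest coordinate of Ptprc. They lie inside the host transcript Gm4258, which runs from 164266 to 62477 bases from that coordinate. Strand was not used for these distances. The model is a long host transcript, the extent of the deletion within it is not given in the sources used here, and the value measures neither mature microRNA nor the deleted part, so it does not check the labels. A second model over the same span was not tested by the authors and stood at 0.272 FPKM in the knockout and 0.0325 FPKM in the wild type. The kit named in the labels does not mark strand. How reads were divided between the 2 models is not given in the sources used here.

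The comparison of the genotypes asked which transcripts differ in thymocytes without these microRNAs. Most of the changed transcripts were lower in the knockout. In the authors' deposited table, 2367 of 13834 tested models (17.1%) had a q under 0.05, of which 247 were higher and 2120 lower in the knockout. The largest rise among the genes named by ratio was that of Il2ra, the alpha chain of the interleukin-2 receptor and a marker of the preceding double-negative stage. It stood at 29.4 FPKM in the knockout and 2.89 FPKM in the wild type, a 10.2-fold difference (log2 3.35, implied standard error 0.32). The share of lower models was 89.6% as deposited, 75.03% after the ratios were centred on their median, and 53.9% among coding genes after a trend with GC content and transcript length was removed. The median log2 ratio of the tested models was -0.17, and the change of a gene group is set against that shift below.

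With 1 model kept per symbol, Il2ra was followed by Ifi203, an interferon-inducible gene of the p200 family, at 57.8 against 14.4 FPKM (4.03-fold), and by Tcrg, a model of the T cell receptor gamma locus, at 14.4 against 3.64 FPKM (3.94-fold). The other 3 called models of that locus were higher by 4.62-fold to 5.80-fold. Those at 4.62-fold and 5.80-fold cover the same span. Pcsk1, a prohormone convertase, was 3.90-fold higher, and Slc15a2, a peptide transporter, was 3.84-fold higher, at 34.1 against 8.87 FPKM. Others among the 12 highest ratios of such models were those of Gng2 (3.63-fold), Tnfsf10 (3.07-fold), which encodes the death ligand TRAIL, Il15ra (2.85-fold), Sypl (2.83-fold), Aim2 (2.62-fold), a cytosolic DNA sensor, and Trps1 (2.48-fold). These 12 had a q between 0 and 0.0424 in the authors' deposited table. After removal of the GC and length trend, Il2ra had a log2 value of 3.19, and 9 of the 11 genes with a usable reference transcript stayed past the threshold, while Il15ra went from a log2 value of 1.51 to 1.75, with an implied standard error of 0.56 and an adjusted p of 0.0756, and Trps1 went from 1.31 to 0.91, with an adjusted p of 0.073. Tcrg had no such transcript. Reads of Ifi203 and of the Tcrg models may be shared with related copies, and the authors' treatment of such reads is not given in the sources used here.

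At the other end, Sox4, a transcription factor of lymphocyte development, was listed at 0 in the knockout and at 30.1 FPKM in the wild type, with a q of 5.87e-05 in the authors' deposited table. A listed 0 in such a table can be a failed estimate, and 32 tested models were at 0 in the knockout and 22 in the wild type, so no fold is given. Hspg2, the proteoglycan perlecan, stood at 0.116 against 5.76 FPKM (log2 -5.63, implied standard error 1.08). Scn4b, a sodium channel subunit, fell to 0.763 from 11.04 FPKM (log2 -3.85, implied standard error 0.33). The others of the 12 lowest were Dpm3 (log2 -4.48), the linker histone H1fx (log2 -4.41), the histone Hist2h2aa2 (log2 -4.20), the ribosomal protein Rps21 (log2 -3.51), Klc3 (log2 -3.33), the splicing regulator Esrp2 (log2 -3.32), Tpgs1 (log2 -3.26), Romo1 (log2 -3.22) and the spliceosome subunit Sf3b5 (log2 -3.16). Scn4b, Esrp2, Hspg2, H1fx and Rps21 stayed past the threshold after removal of the GC and length trend, with log2 values of -3.29, -2.54, -4.42, -3.36 and -2.38. Hist2h2aa2, Klc3, Tpgs1 and Romo1 did not, at adjusted p values of 0.304, 0.585, 0.117 and 0.197. Dpm3 and Sf3b5 had no usable reference transcript, and Sox4, listed at 0 in the knockout, had no log2 ratio to correct. Histone and ribosomal protein genes have close copies whose reads could have been split.

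**Figure D1:**
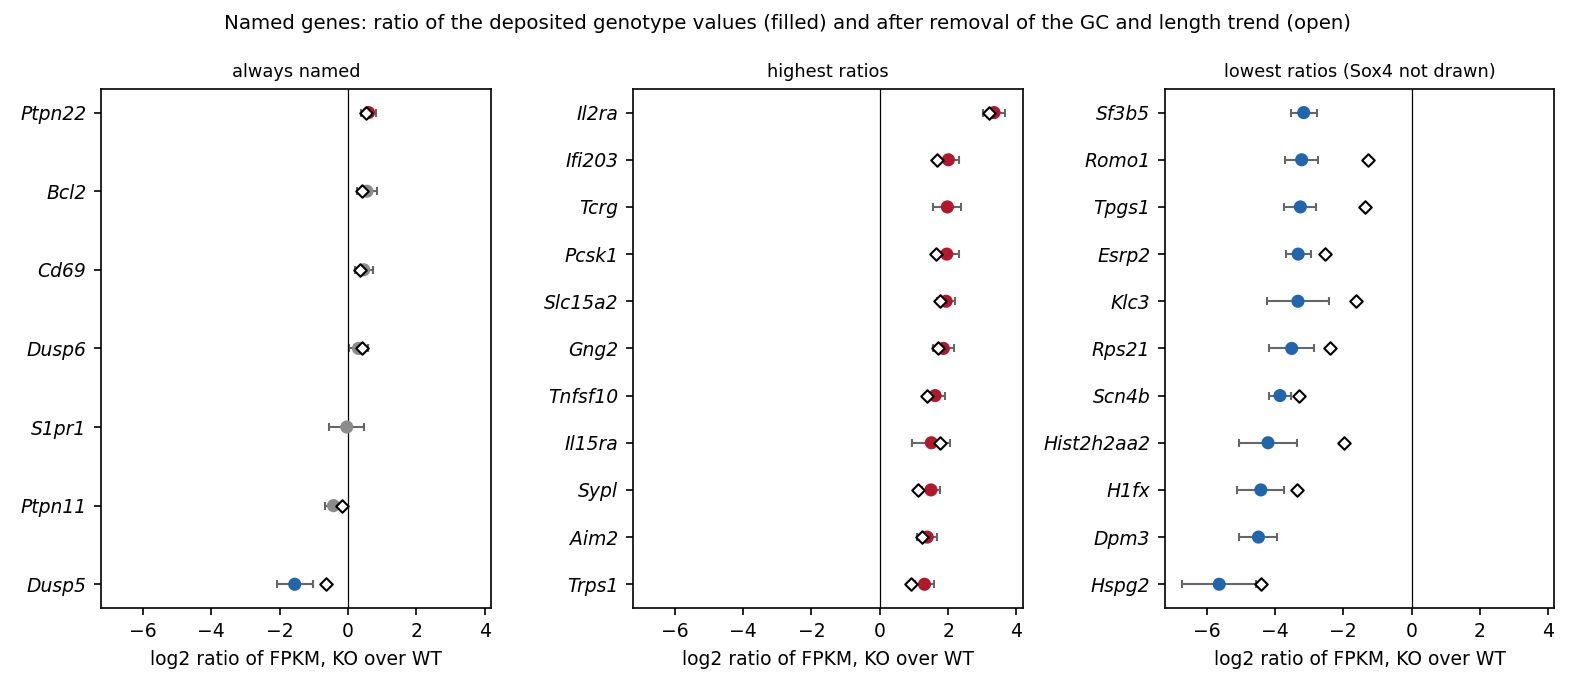
Log2 ratio of the authors' FPKM, knockout (KO) over wild type (WT), for 7 genes always named, 11 of the 12 highest and 11 of the 12 lowest. Filled points are deposited ratios (red higher, blue lower, grey not past the threshold) with bars of 1 standard error implied by the deposited test statistic, and open diamonds are values after removal of the GC and length trend. Il2ra lies at 3.35 and Hspg2 at -5.63.

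Among the genes reported in the literature as miR-181 targets, Ptpn22, a phosphatase of T cell receptor signalling, stood at 101 against 66.2 FPKM (log2 0.61, implied standard error 0.23, q = 0.0432 in the authors' deposited table). Dusp5, a phosphatase of ERK, was lower in the knockout at 4.38 against 12.9 FPKM (log2 -1.56, implied standard error 0.53, q = 0.0234 in the authors' deposited table). Of 19 tested members, 2 rose, 1 fell and 16 did not pass the threshold. The last group included Bcl2 at 3.13 against 2.13 FPKM (q = 0.176), Cd69 at 34.5 against 24.996 FPKM (q = 0.26), Dusp6 at 10.3 against 8.34 FPKM (q = 0.531), Ptpn11 at 14.7 against 19.7 FPKM (q = 0.277) and S1pr1 at 0.304 against 0.310 FPKM (q = 0.992), each q from the authors' deposited table. The counts were the same when adjusted over the list alone. The median log2 ratio of the list was 0.06 and its mean -0.02, and the median lay at percentile 97.2 of random lists matched on expression and 77.5 of those matched on GC content as well. After the GC and length trend was removed, Ptpn22 and Dusp5 had log2 values of 0.54 and -0.64 with adjusted p values of 0.296 and 0.863.

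The deposited ratios followed the base composition of the transcripts. Coding genes rich in A and T, such as Ifi203 at 38.1% GC, had mostly positive ratios, and genes rich in G and C, such as Akt1 at 59.7% GC, had mostly negative ones. Over 8742 coding genes with a mean of at least 1 FPKM, Spearman's rho of the log2 ratio with transcript GC content was -0.765, a correlation across genes, which are not independent replicates. With the genes sorted into 10 groups by GC content, the median log2 ratio fell from 0.29 in the group with the lowest GC to -1.32 in the group with the highest. In the first group 5.83% of the genes were called higher and 0.229% lower, and in the last none was called higher and 72.0% were called lower. The rho with transcript length was 0.375. A spline of GC content and length accounted for 59.4% of the variance of the log2 ratio across genes, and SD across genes dropped from 0.69 to 0.44 with its removal. Of the coding genes, 1836 were called before the removal (135 higher, 1701 lower) and 152 after it (70 higher, 82 lower). All 82 lower genes and 25 of the 70 higher ones had been called in the same direction before.

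**Figure D2:**
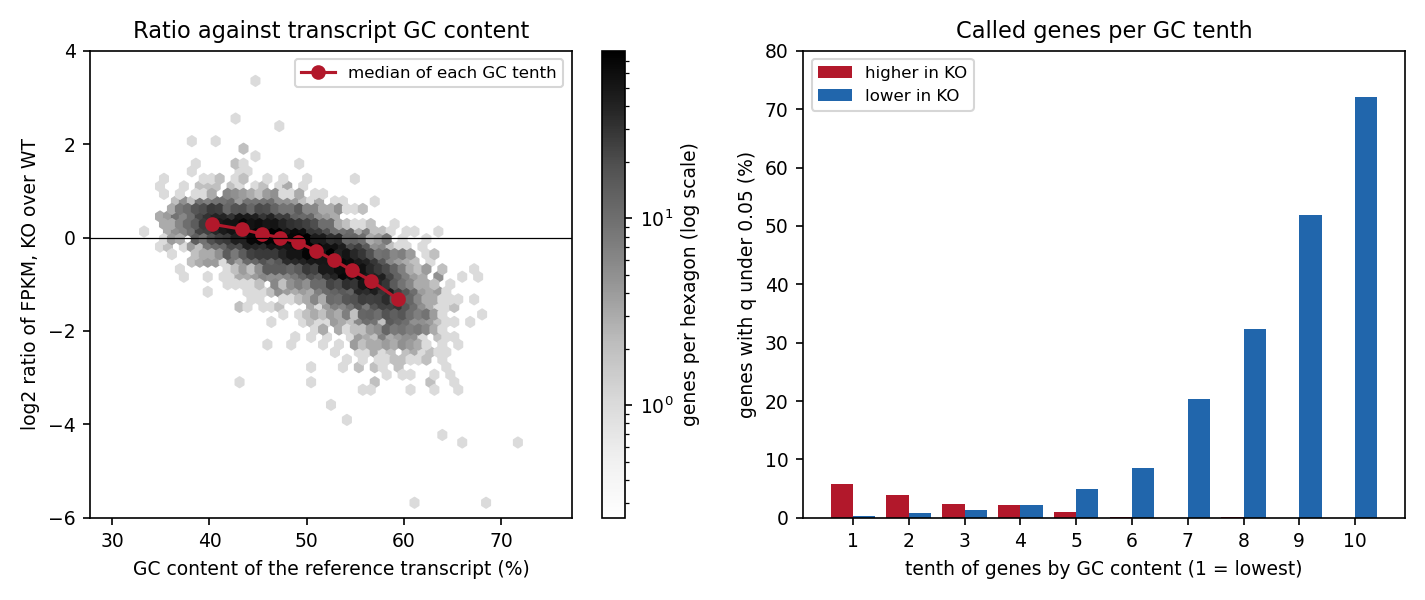
Left, log2 ratio of FPKM (knockout, KO, over wild type, WT) against GC content of the reference transcript (%) for 8742 coding genes, as the number of genes per hexagon on a log scale, with the median of 10 groups by GC content. Right, percent of the genes in each group with a q under 0.05, higher (red) or lower (blue) in the knockout; the share of lower genes goes from 0.229% to 72.0%.

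Genes of protein synthesis and respiration were lower in the knockout as groups. Of 79 tested cytosolic ribosomal proteins, 41 fell and none rose, and 50 fell when adjusted over the list alone. Their median log2 ratio was -0.98, below all 10000 random lists matched on expression. Rpl41 stood at 158 against 1038 FPKM and Rpl8 at 112 against 472 FPKM. Of 82 respiratory chain subunits, 41 fell and none rose (47 lower when adjusted over the list alone), with a median of -0.85, again below all random lists. Ndufb7 of complex I stood at 15.05 against 99.2 FPKM, Ndufa7 at 6.67 against 43.5 FPKM and Uqcrq of complex III at 1.18 against 10.2 FPKM. Both groups also lay below all random lists matched on GC content, and after removal of the GC and length trend their medians were -0.38 and -0.20, with 11 ribosomal proteins and 2 respiratory subunits, Uqcrq and Ndufa7, still called.

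Glycolytic enzymes were lower as well, with 9 of 17 fallen (10 when adjusted over the list alone) and none risen. Ldhb stood at 78.8 against 174 FPKM, Aldoa at 16.7 against 43.3 FPKM and Gapdh at 63.6 against 128 FPKM. Their median of -0.81 lay at percentile 0.38 of lists matched on expression, at 5.76 of those matched on GC content and, with a median of -0.09, at 12.4 after the trend was removed, where Gapdh turned to 0.03 and no member was called. In the cell cycle list 7 of 22 members fell (9 when adjusted over the list alone) and none rose. The replication clamp Pcna stood at 70.6 against 168 FPKM, Mcm5 at 22.1 against 49.8 FPKM and Mcm2 at 26.1 against 56.1 FPKM, while Mki67 stood at 213 against 184 FPKM (q = 0.76 in the authors' deposited table). The median of the list was -0.57, at percentile 1.77, but at 6.99, inside the central 95%, among lists not matched on expression. It lay at 0.02 among lists matched on GC content and at 0.12 after the trend was removed, where only Pcna, at -1.19, was still called. Nucleotide synthesis genes had 6 of 25 members lower (8 when adjusted over the list alone), among them Shmt2, Impdh1 and Cad, and none higher. Their median of -0.55 lay at percentile 6.02, at 0.415 when matched on GC content and below all random lists after the trend was removed, where Impdh1 turned to 0.06 and no member was called.

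In the citric acid cycle 5 of 16 genes fell (7 when adjusted over the list alone), among them Mdh2, Sdhb, Sdhc and Sdhd, with a list median of -0.45 at percentile 8.75, and at 3.70 when matched on GC content. In the pentose phosphate pathway 3 of 9 fell (4 when adjusted over the list alone), the sugar-phosphate enzymes Pgls, Taldo1 and Tkt, with a median of -0.32 at percentile 33.7. In cholesterol synthesis 3 of 15 fell (4 when adjusted over the list alone), among them Mvd and Mvk, with a median of -0.44 at percentile 30.6. No member of these 3 lists rose. After removal of the trend, the medians of the 3 lists were -0.15, -0.14 and -0.01, at percentiles 1.77, 10.6 and 56.5, so that the citric acid cycle then lay outside the central 95% of random lists, and of their members only Tkt, at -0.95, was still called.

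Most genes that define the double-positive stage did not pass the threshold. Cd4 stood at 907 against 732 FPKM, Cd8a at 836 against 906 FPKM and Rag2 at 162 against 134 FPKM, and none of these passed the threshold. Of 15 tested identity genes, Aqp11 (72.3 against 137 FPKM) and the survival gene Bcl2l1 (62.7 against 118 FPKM) fell and none rose (3 lower and none higher when adjusted over the list alone), with a median of -0.27 at percentile 42.8. After the GC and length trend was removed Aqp11 stayed past the threshold at -0.84, and Bcl2l1 did not, at -0.10. Of the double-negative markers, Il2ra rose and Ptcra, the pre-T cell receptor alpha chain, fell to 9.59 from 26.1 FPKM, and the other 7 of 9 did not pass, with the same counts when adjusted over the list alone. The median of that list was -0.47 at percentile 34.4, and it turned to 0.09 after the trend was removed, where Il2ra was still called and Ptcra was not, going from -1.45 to -0.42, with an adjusted p of 0.763. No NKT lineage gene of 8 tested passed, over all genes or adjusted over the list alone, and the median of -0.06, at percentile 75.1, turned to 0.11 when centred. It lay at percentile 16.2 of lists matched on GC content, and at 11.2 with a median of -0.13 after the trend was removed.

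Of 23 T cell receptor signalling genes, Ptpn22 rose and 7 fell, and 8 fell when adjusted over the list alone. The kinase Zap70 stood at 28.8 against 75.3 FPKM, the adaptor Lat at 283 against 574 FPKM and the kinase Csk at 37.9 against 82.6 FPKM. After removal of the GC and length trend Lat and Csk turned to 0.23 and 0.20, Zap70 was at -0.10, no member was called, and the median of the list moved from -0.26, at percentile 40.8, to 0.06. Among genes induced by receptor signalling, Cd53 rose to 17.5 from 7.12 FPKM. Cd5 (65.6 against 105 FPKM) and Egr1 (34.0 against 53.3 FPKM) fell as deposited and turned to 0.19 and 0.27 after the trend was removed, while Cd53 was still called at 1.12. The other 15 of 18 did not pass, with the same counts when adjusted over the list alone. The median of that list was -0.10, at percentile 84.2, and turned to 0.07 when centred and to 0.18 after the trend was removed.

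In the PI3K, Akt and mTOR pathway, 2 genes rose and 2 fell, of 24 tested, with the same counts when adjusted over the list alone. Those that fell were Akt1 (26.3 against 73.8 FPKM) and Rptor (5.89 against 13.3 FPKM), neither of which stayed past the threshold after the GC and length trend was removed, at adjusted p values of 0.971 and 0.867. The median of -0.12, at percentile 74.8, turned to 0.05 when centred. Of 14 FoxO-responsive genes, 2 rose, among them Sesn3 (23.6 against 12.9 FPKM), and Bcl6 (41.8 against 75.4 FPKM) fell, with the same counts when adjusted over the list alone. The median of that list was 0.00 with a mean of -0.02, at percentile 92.3. No member was called after the trend was removed, where Sesn3 went from 0.87 to 0.65, with an adjusted p of 0.2497, and Bcl6 from -0.85 to -0.56, with an adjusted p of 0.368. Of 19 apoptosis genes, Mcl1 rose to 168 from 110 FPKM, and Bad, Bax, Bbc3, Bak1 and Bcl2l1 fell. Adjusted over the list alone, 2 were higher and 7 lower. The median was -0.32 at percentile 41.8 and turned to 0.12 after the trend was removed, where no member was called. Mcl1 went from 0.62 to 0.69 with an implied standard error of 0.21 and an adjusted p of 0.0607, Bad from -2.04 to -0.46, Bbc3 from -1.75 to -0.02 and Bcl2l1 from -0.91 to -0.10, and Bax and Bak1 turned to 0.13 and 0.11.

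Interferon-stimulated genes lay higher in the knockout as a group. Their median log2 ratio over 13 tested genes was 0.49, above all random lists under both matchings, and 0.62 after the GC and length trend was removed, with 12 of 13 members above 0. Singly, only Rtp4 rose, to 6.12 from 3.30 FPKM, and Bst2 fell to 6.81 from 16.8 FPKM, with the same counts when adjusted over the list alone. Neither was called after the trend was removed, where Rtp4 went from 0.89 to 1.07 with an implied standard error of 0.33 and an adjusted p of 0.0626, and Bst2 from -1.31 to -0.17, with an adjusted p of 0.999. Rsad2 stood at 1.09 against 0.563 FPKM (q = 0.0733 in the authors' deposited table) and Ddx58, which encodes RIG-I, at 18.8 against 11.7 FPKM (q = 0.0954 in the authors' deposited table). Among the immediate early and stress genes, Fos, Junb, Dusp1 and Egr1 fell, of 9 tested, with the same counts when adjusted over the list alone. Their median of -0.95 lay at percentile 2.75, at 1.62, outside the central 95%, among lists not matched on expression, at 13.7 with no filter on low values and at 12.1 when matched on GC content. After the trend was removed the median of the list was -0.30, at percentile 4.71. Junb then went from -1.93 to -0.31 and Dusp1 from -0.95 to -0.22, and no member was called. Fos, with a mean under 1 FPKM, had no call of its own there. Of 225 tested C2H2 zinc finger genes, 9 rose and 27 fell, with the same counts when adjusted over the list alone. Zfp760 stood at 2.54 against 0.997 FPKM and Zfp260 at 49.4 against 27.6 FPKM, while Zfp219 stood at 6.39 against 30.9 FPKM. The median was 0.09 and the mean -0.11, and the median lay above all random lists under both matchings. None of these genes was called after the trend was removed.

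The markers of other cell types that passed were low in both genotypes, and most of them were lower in the knockout. Most markers that did not pass were low as well, with exceptions. Among the exceptions, Pecam1 of the thymic epithelial and stromal list stood at 51.5 against 55.5 FPKM. Cd79b of the B cell list stood at 15.7 against 20.1 FPKM. Cd74, the invariant chain of antigen-presenting cells, stood at 1.99 against 7.89 FPKM, the epithelial marker Epcam at 0.932 against 2.30 FPKM, the macrophage genes C1qb at 0.355 against 1.48 FPKM and Itgam at 1.02 against 2.11 FPKM, and the globin Hba-a2 at 0.213 against 0.948 FPKM. These made up the calls among 5 dendritic cell genes, 3 thymic epithelial genes, 6 macrophage genes and 3 erythroid genes tested, and the counts were the same when adjusted over the list alone. The kinase gene Blk, which stood on both the B cell and the gamma-delta T cell list with 2 tested genes each, was higher at 0.639 against 0.191 FPKM and was the only call on either, also when adjusted over the list alone. Macrophage and dendritic cell lists had medians of -1.21 and -1.34, at percentiles 8.91 and 3.50 of lists matched on expression, 6.32 and 1.35 of those matched on GC content, and 0.660 and 1.07 of those not matched on expression. After the trend was removed their medians were -0.76 and -0.89, at percentiles 2.98 and 0.565. Of the called markers, Cd74, Epcam and Itgam had a value of their own after the removal, going from -1.98 to -0.95, -1.30 to -0.80 and -1.05 to -1.02, and none of them was called, at adjusted p values of 0.321, 0.444 and 0.198. No mitochondrially encoded gene was tested.

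**Figure D3:**
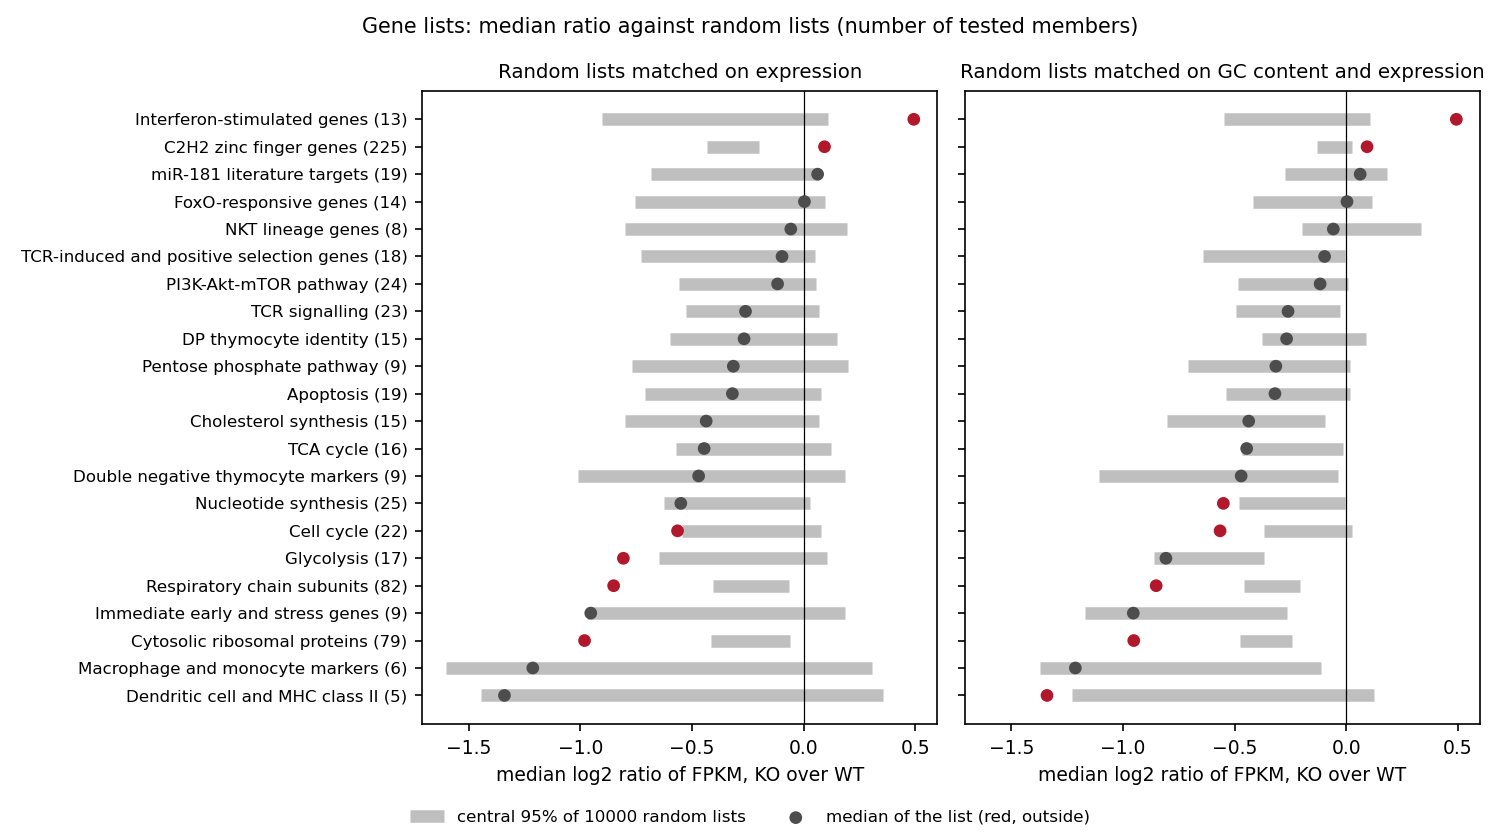
Median log2 ratio of FPKM (knockout, KO, over wild type, WT) of 22 gene lists, with the number of tested members, as points, and the central 95% of 10000 random lists of the same size as bars, matched on expression (left) or on GC content and expression (right). Red points lie outside the bars; interferon-stimulated genes (0.49) lie above them and cytosolic ribosomal proteins (-0.98 on the left) below them in both panels.

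The deletion removes microRNAs that bind sites in the 3′ untranslated region (UTR) of messenger RNAs, so genes were grouped by the best match to the miR-181 seed in the GRCm38 annotation. The 488 genes with the full site TGAATGTA, among them Cd69, Bcl2, Sesn3 and Tnfsf10, had a mean log2 ratio of 0.10, against -0.45 in the 6785 genes without a site. The difference of 0.56 lay above those of all 50 shuffled seeds, which ranged from 0.34 to 0.53. After the GC and length trend was removed it was 0.12, above a range of -0.10 to 0.05 for the shuffled seeds. By then 65.0% of the genes with the full site had a value above 0, and 48.3% of those without a site.

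Genes whose best match was the 7-base site TGAATGT, 1015 in number, or GAATGTA, 410 in number, differed from those without a site by 0.41 and 0.40 as deposited, above 42 and 34 of the 50 shuffled seeds. After removal of the trend the differences were 0.04 and 0.05, above all 50 in both cases. Il2ra, Ptpn22, Slc15a2 and Ifi203 carried no match of TGAATGT. Matches in the coding sequence went with higher ratios, from a mean corrected log2 value of -0.02 in 7328 genes without one to 0.16 in 103 genes with 3 or more, of which 52 were C2H2 zinc finger genes. Shuffled seeds were compared only for the 3′ UTR, so the values for the coding sequence do not separate the matches from the zinc finger genes. These are comparisons across genes, which are not independent replicates, and sites of other microRNAs were not analysed here.

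**Figure D4:**
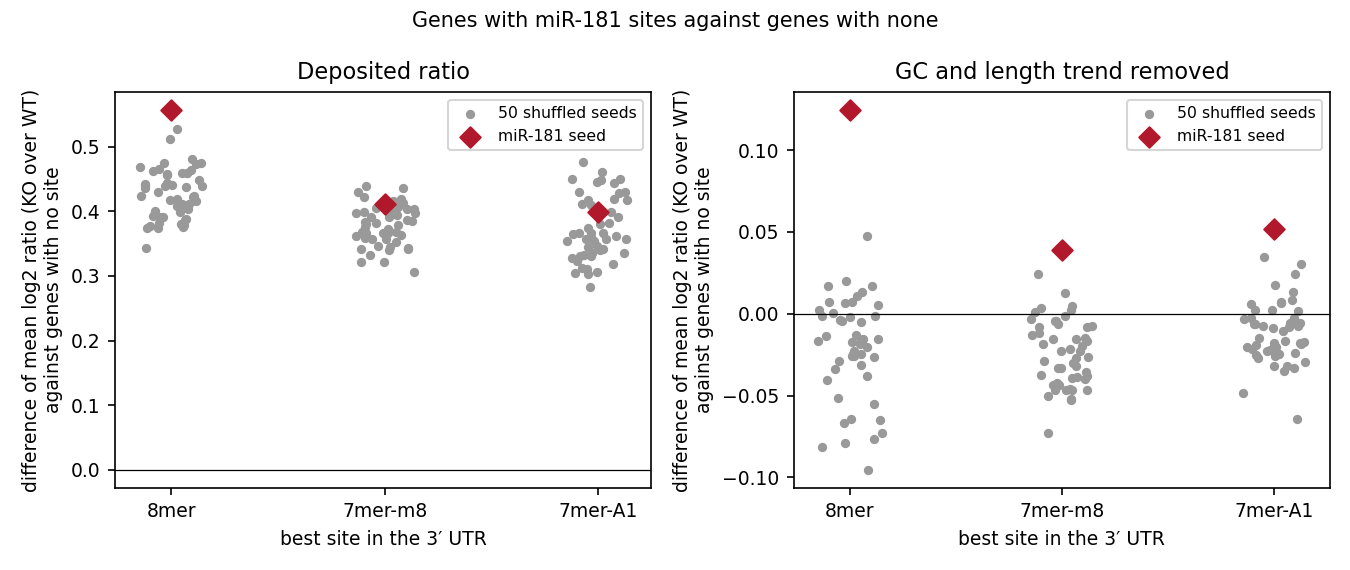
Difference of the mean log2 ratio (knockout, KO, over wild type, WT) between genes with a site and 6785 genes without one, for 3 kinds of site in the 3′ UTR, with the miR-181 seed in red and 50 shuffled seeds in grey. Left, deposited ratios, where the full site lies at 0.56; right, after removal of the GC and length trend, where it lies at 0.12.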

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

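Centring, the restriction to coding genes, removal of the GC and length trend and leaving out overlapping models were chosen after the data had been seen. With a q under 0.01, 1505 models changed, 103 higher and 1402 lower, by the stricter threshold itself. With an absolute log2 ratio of at least 1, 115 were higher, again by the threshold. Centring on the median, which raises every ratio, gave 496 higher. Coding genes of at least 1 FPKM gave 135 higher, and models sharing no locus gave 151 higher, both with fewer models tested. Removal of the GC and length trend left 152 changed, 70 higher and 82 lower, and the cause was not tested in this comparison. Of the named genes with a value after it, 26 kept their call or lack of one, 49 lost it in the same direction, and 7 that were lower turned above 0, by log2 values of 0.13 for Bax, 0.19 for Cd5, 0.20 for Csk, 0.27 for Egr1, 0.029 for Gapdh, 0.057 for Impdh1 and 0.23 for Lat; since ratios fell with GC content, the removal itself raises genes of high GC. Total counts were within 1.5 times the main one with no filter on low values (2086), a mean of at least 5 FPKM (1807), an absolute log2 ratio of at least 1 (1704) and centring (1986). The number of lists outside the central 95% was 6, and 6 to 8 under the alternatives. The difference for the full miR-181 site stayed above all 50 shuffled seeds in all 5 settings, from 0.12 to 0.57. No paired analysis was possible because the table gives 1 value per genotype. For the same reason DESeq2, its size factors in edgeR or for the lists, a pseudocount of 0.1, limma without the trend or with sample weights, camera with an estimated correlation, leaving out each library in turn and other splits of the samples were not run. Depth is unknown, so it was not used to weigh any value.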

Other observations

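The removal of the GC and length trend was chosen after the ratios had been seen, as were the genes named in the first 2 paragraphs. So was the test in zinc finger genes of a metabolic, ribosomal and cell cycle programme, while the predictions for the other tests further on were written before the tested values were seen. Several lymphocyte genes were called higher in the knockout both as deposited and after the trend was removed. Cd93 stood at 2.35 against 0.427 FPKM (corrected log2 2.36), Stat4, a transducer of interleukin-12 signalling, at 35.8 against 16.1 FPKM (corrected log2 1.08), the protease Gzma at 55.2 against 31.3 FPKM (corrected log2 1.08), Il17rb at 17.6 against 8.78 FPKM (corrected log2 1.39) and Ly75, an endocytic receptor, at 11.8 against 5.15 FPKM (corrected log2 1.16). All 4 called models of the T cell receptor gamma locus were higher, from 3.94-fold to 5.80-fold. The models at 4.62-fold and 5.80-fold cover the same span, so they are not separate observations. Ifi209 (51.3 against 21.5 FPKM), Aim2 and Ifi203 lie within 1 stretch of chromosome 1, between 175392277 and 175961922 in mm9. Of the 152 genes called after the trend was removed, 6 higher and 5 lower lay among 507 genes of chromosome 1.

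Among the genes called lower both ways, Scn2b (1.66 against 5.55 FPKM), Scn4b and Il10ra (1.82 against 6.66 FPKM) are neighbours on chromosome 9, between 44918067 and 45077247 in mm9. Calcium channel genes Cacna1e (1.64 against 7.76 FPKM) and Cacnb3 (2.45 against 14.6 FPKM) were on the same side, as were Id3, an inhibitor of E proteins that is induced by receptor signalling, at 6.57 against 40.5 FPKM (corrected log2 -1.67), the matrix protein gene Smoc1 at 3.71 against 22.6 FPKM (corrected log2 -2.04), the receptor gene Tnfrsf13b at 1.25 against 8.34 FPKM (corrected log2 -2.49) and the linker histone H1f0 at 4.45 against 21.7 FPKM (corrected log2 -1.86).

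The fall of the ratio with GC content was weighed first. A programme of metabolic, ribosomal and cell cycle genes as the whole cause is argued against by a rho of -0.823 in 196 zinc finger genes, none of them on those lists, with a bootstrap interval from -0.868 to -0.761, while the rho of -0.769 in the 8483 of 8742 genes outside the lists decides nothing, since the lists hold too few genes to move it. For regulation of protein-coding genes alone, 40 non-coding RNA genes were examined. Their rho was -0.572, with a bootstrap interval from -0.732 to -0.335. Non-coding genes that overlap coding genes were not left out, and the kit does not mark strand. Reads of coding genes may therefore enter these values, which cannot decide the question. A GC-dependent difference in extraction, library preparation or sequencing between the genotypes would give a trend in all groups. The weakest rho among 5 groups of expression and the zinc finger genes was -0.735. An effect of the genotype by base composition would give the same, so this value does not favour a technical cause. Such an effect of the genotype stays open and was not tested, and which library was extracted by which method is not given in the sources used here.

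The higher ratio of genes with the full miR-181 site was weighed next. GC content and length as the whole cause are argued against by the difference of 0.125 after their trend was removed, above the highest of 50 shuffled seeds at 0.05. Base composition of the UTR is argued against by the ranking of 14745 words of 7 bases, where 0.102% lay above TGAATGT, at rank 16, and GAATGTA had rank 6. By a scaled difference, or with the 12246 words found in at least 200 UTRs, these words had ranks 2 and 1. The values are in line with a loss of repression by miR-181, as a hypothesis found and tested on the same table, and other microRNAs or proteins that bind this word were not tested.

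The host transcript of the deleted microRNA genes, 46.6-fold higher in the knockout, raised the question whether the genotype columns had been exchanged. If loss of miR-181 raises genes with the full site, exchanged columns would place them below those without. They lay above by 0.125 after the trend was removed. The paragraph before read the same value with the labels taken as given, so it is not separate support for the labels. A transcript that is no longer cut into microRNA may accumulate, or the altered allele may be expressed more, and neither was tested.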
